A study of Homo sapiens with 7 samples.

How the data were processed

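Basal epithelial cells were sorted by flow cytometry from fresh prostate tissue after overnight enzymatic digestion, and total RNA was extracted from the sorted cells on spin columns, per the labels' protocols. There were 7 libraries from 7 patients, 3 with basal cell hyperplasia and 4 without. The p-values of single genes and of list means therefore measure differences against the spread between patients. Groups were taken from the phenotype label. Replicate numbers were given in accession order and pair nothing.

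The deposited values were FPKM for 62016 Ensembl gene identifiers in the 7 libraries, in 1 table made by the authors. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, Trimmomatic 0.32, TopHat2, Bowtie2 2.2.3, SAMtools 0.1.19, Cufflinks 2.2.1 and Cuffnorm, on genome build GRCh37. Their order and settings, the gene annotation, the scaling Cuffnorm applied and the use of strand are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical genes and pseudogenes could be split in either direction. Names were matched for 50381 identifiers through tables of gene names and an annotation of another build, which was used for names and gene classes and never for coordinates. Every column of values was mapped to a sample. FPKM summed to between 1542295 and 2961901 per library, and mitochondrial tRNAs took 42.8% to 54.8% of that sum.

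There were 25235 genes listed at 0 in every library. Another 241 genes were listed at 0 in at least 1 library although their median over the libraries was above 10 FPKM, of which 122 were small or ribosomal RNAs, 110 had no matched name, 5 were pseudogenes, 4 were of other classes and 0 were protein-coding. A 0 of a gene outside the protein-coding class is therefore called listed at 0. Depth was not recorded. The spacing of the values under 0.5 FPKM gave a rough relative depth per library, from 0.973 to 1.80 times that of non-BCH replicate 4, and no counting intervals could be given.

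The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend on log2(FPKM + 1), two-sided, over genes with a mean of at least 1 FPKM over the 7 libraries, without covariates. Calls had a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are BCH minus non-BCH on the log2(FPKM + 1) scale with their standard errors, and understate the change of genes with low values. Values in FPKM are means with SD, n = 3 for BCH and n = 4 for non-BCH. Gene lists were tested with limma's camera at its preset correlation of 0.01, with camera at a correlation estimated per list, and with fry, which tests whether a list's genes move on balance in one direction. Lists with fewer than 5 tested genes were left out of these tests. At the preset correlation camera takes the genes of a list as nearly independent. Its p-values then do not measure how a list varies between patients. Marker lists of cell types were averaged per library and compared by an exact two-sided permutation test over the 35 splits of the 7 libraries. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

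The 31 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, and further choices are named where they appear. The lists covered cornified envelope, stress keratin, squamous and hillock, epidermal transcription factor, epidermal lipid and antimicrobial genes, markers of basal, luminal, club, urothelial, neuroendocrine, seminal vesicle, leukocyte, stromal and endothelial cells, and genes of the cell cycle, immediate early response, cytokines, interferon, androgen, steroid, retinoid, Notch, Wnt and Hedgehog, ErbB, matrix, glycolysis, oxidative stress, ribosome, mitochondrial genome and oxidative phosphorylation. LOR, CD24, CCL5, SRD5A2, ACACA and SRXN1 were among the list genes not matched to a row. Named genes were the 10 with the largest rise and the 10 with the largest fall among called genes without overlap between the groups, up to 4 called members of each list (over all genes or, failing that, over the list alone), the 2 members of lowest p where none passed, and EPCAM, ITGA6, DPP4, KRT5, KRT14, TP63, KLK3, PTPRC and COL1A1. A gene that this rule takes is not reported here. Sex-linked marker genes, genes that follow a common inherited deletion, immune receptor segments, small RNAs and placeholder names were counted and passed over.

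The gene test was tested on simulated data with the means and spread of the 17527 tested genes in 3 against 4 libraries, with 200 genes changed in each of 5 runs. It recovered 76.8% of genes changed by 2 and 96.6% of genes changed by 4 on the log2 scale. Of its calls 4.04% were false, and it made 0 calls in 1 run with no change simulated. A list shifted by 1 on the log2 scale was called in 5 of 5 runs, and 1 other list was called over the runs. The changed genes had a mean log2(FPKM + 1) above 2, and the noise was drawn independently for each gene. The simulation thus left out the correlation between genes, and its false-call rates do not carry over to the real libraries. There, splits other than the real one called up to 17 genes and 18 lists. Alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 FPKM, quantile normalization, median-ratio rescaling, rescaling to TPM, a robust and an untrended variance model, array weights, an adjusted p under 0.1, and each library left out in turn. Protein-coding genes alone were added after seeing the data.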

Results

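Basal cell hyperplasia (BCH) is an overgrowth of the basal layer of prostate glands. Gene expression was measured by RNA sequencing in basal epithelial cells sorted from fresh prostate tissue of 3 patients with BCH and 4 patients without it (non-BCH), with 1 library per patient. The sort kept cells positive for CD326 (EPCAM), high for CD49f (ITGA6) and negative for CD26 (DPP4), which was meant to leave out leukocytes, stroma and luminal epithelium. The deposited table gave FPKM for 62016 genes, of which 17527 had a mean of at least 1 FPKM over the 7 libraries and were tested. It holds no counts, so the absolute depth was unknown. The spacing of the lowest values put the relative depths roughly between 0.973 and 1.80 times that of non-BCH replicate 4, BCH replicate 3 being the deepest. Between 15757 and 16656 genes reached 1 FPKM in a library.

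The first principal component separated the groups and held 31.7% of the variance, with scores of 31.6 to 102 in BCH and -62.0 to -35.7 in non-BCH. The second held 16.9%, and both groups were spread along it. The median Spearman correlation across genes was 0.860 within BCH, 0.850 within non-BCH and 0.822 between the groups. Genes are not independent replicates, so these correlations describe the libraries only.

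**Figure D1:**
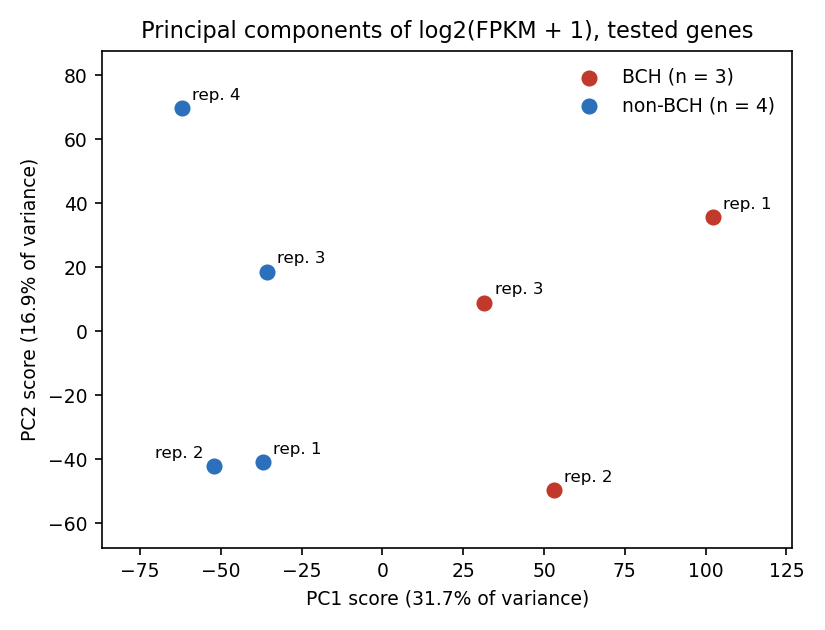
Scores of the 7 libraries on the first and second principal components of log2(FPKM + 1) over the 17527 tested genes, in arbitrary units, each point being 1 patient's library (rep. is the replicate number). The 3 BCH libraries lay at 31.6 or above on the first component and the 4 non-BCH libraries at -35.7 or below.

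The markers of the sort and of basal cells were present in both groups. ITGA6 averaged 138 ± 43.4 FPKM (SD, n = 3) in BCH and 107 ± 23.0 (SD, n = 4) in non-BCH, and EPCAM 57.6 ± 15.8 and 90.3 ± 18.6. DPP4 was under the filter, at 0.255 ± 0.139 and 0.559 ± 0.548 FPKM. The basal keratin KRT5 averaged 1694 ± 750 FPKM in BCH and 1610 ± 733 in non-BCH, its partner KRT14 274 ± 186 and 323 ± 151, and TP63, the transcription factor of basal cells, 26.8 ± 6.45 and 22.0 ± 4.26. The libraries of the groups overlapped for each of these genes, and none of those tested passed over all genes. PTPRC, the leukocyte antigen CD45, was also under the filter, at 1.29 ± 0.745 and 0.684 ± 0.395 FPKM.

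The main comparison asked how basal cells from BCH differed in expression from those of prostates without it. The suprabasal keratins KRT13 and KRT4, the transglutaminase TGM5, the cornified envelope protein CNFN and the serine protease inhibitor SPINK7 rose in BCH, KRT13 to 3078 ± 1761 FPKM (SD, n = 3) from 260 ± 195 (SD, n = 4) in non-BCH. KRT13 passed narrowly (adjusted p = 0.0471, limma). With 1 library left out its adjusted p reached 0.146 and that of KRT4 0.136, whereas TGM5, CNFN and SPINK7 stayed under 0.05 (limma). Over all genes, 3 of 20 cornified envelope genes and 5 of 31 squamous genes rose, 2 to 4 and 0 to 4 with 1 library left out, and both lists had adjusted p = 0.110 with an estimated correlation (camera, limma). The intermediate filament VIM, the calcification inhibitor MGP, the collagen COL6A2, the acute-phase inhibitor SERPINA3 and the methyltransferase NNMT fell, MGP to 50.5 ± 11.9 FPKM from 426 ± 143. The adjusted p of VIM was 0.0463 and reached 0.121 with 1 library left out (limma). Of these genes NNMT alone stayed under 0.05 in each such fit. Over all genes, 5 of 21 fibroblast and smooth muscle genes and 2 of 34 matrix genes fell, 0 to 2 of each with 1 library left out, and these lists also had adjusted p = 0.110 with an estimated correlation (camera, limma). KRT5, KRT14 and TP63 did not pass the test.

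In all, 143 genes passed limma's moderated test on log2(FPKM + 1) with Benjamini-Hochberg adjustment, 92 higher and 51 lower in BCH, and 3694 genes had an unadjusted p under 0.05. After rescaling to TPM the balance turned, to 46 higher and 97 lower, and with 1 library left out 39 to 267 genes passed. In each of the 143 the groups did not overlap. Over all tested genes, 3563 (20.3%) had no overlap, where chance gives 5.71%. Of the 143, 104 were protein-coding (62 higher, 42 lower), 8 were small or ribosomal RNAs, 5 were pseudogenes, 10 were of other classes and 16 had an identifier without a matched name. A small RNA, pseudogene or unmatched gene could be listed at 0 in some libraries, and 21 of the 143 calls had at least 1 such library, none of them protein-coding.

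Among the 10 genes with the largest rise, SPINK7 went from 0.777 ± 0.230 to 23.3 ± 4.33 FPKM (log2 fold change 3.77 ± 0.21, SE; adjusted p = 0.000423, limma). LYPD3, a GPI-anchored protein of squamous epithelium, averaged 326 ± 120 FPKM in BCH and 29.7 ± 14.02 in non-BCH, a log2 fold change of 3.49 ± 0.44 (adjusted p = 0.0274, limma). With 1 library left out the adjusted p of LYPD3 reached 0.0846, and that of SPINK7 stayed at 0.00278 or below (limma). ECM1, a secreted matrix protein also made by keratinocytes, rose by 3.62 ± 0.39 on the log2 scale, to 103 ± 37.3 FPKM from 7.74 ± 4.05. PLBD1, a phospholipase-like protein, rose by 3.28 ± 0.53 and the neuropeptide gene NMU by 3.04 ± 0.38. Their adjusted p were 0.0471 and 0.0271 and reached 0.151 and 0.0677 with 1 library left out (limma). The pseudogene CYP2AB1P stood at 17.2, 19.97 and 13.5 FPKM in the BCH libraries and at 2.16, 0.842, 0.233 and a listed 0 in the non-BCH libraries. Reads of a pseudogene can be shared with related genes, so its value is uncertain.

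Among the 10 with the largest fall, SERPINA3 dropped from 335 ± 213 to 25.4 ± 8.79 FPKM (log2 fold change -3.50 ± 0.50; adjusted p = 0.0333, limma), and NNMT from 86.3 ± 21.6 to 7.23 ± 2.01 (log2 fold change -3.40 ± 0.28; adjusted p = 0.00364, limma). With 1 library left out the adjusted p of SERPINA3 reached 0.121, and that of NNMT stayed at 0.0167 or below (limma). The secreted factor TGFB2 fell by 2.80 on the log2 scale, from 82.9 ± 17.9 to 12.3 ± 6.74 FPKM. GALNT15, a glycosyltransferase, fell by 2.84, FHL1, a LIM-domain protein, by 2.50, and GPX3, a secreted glutathione peroxidase, by 2.31. The adjusted p of GALNT15, FHL1 and GPX3 were 0.0478, 0.0281 and 0.0367 (limma). With 1 library left out they reached 0.170, 0.0759 and 0.128 (limma). VIM fell by 2.51, from 104 ± 61.0 to 15.8 ± 3.01 FPKM, and COL6A2 by 2.29. The pseudogene HMGN1P38 averaged 0.0851 ± 0.0449 FPKM in BCH and 5.65 ± 0.516 in non-BCH, with the same uncertainty over shared reads.

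The keratinocyte groups were higher in BCH. Of the 20 tested genes of the cornified envelope and suprabasal layers, 3 rose over all genes and 13 adjusted over the list alone, none fell, and the median log2 fold change was 1.83. TGM5, which cross-links the envelope, went from 4.58 ± 1.16 to 64.4 ± 32.0 FPKM (log2 fold change 3.47 ± 0.34), CNFN from 3.67 ± 0.428 to 47.6 ± 5.54 (3.38 ± 0.17) and the protease inhibitor CSTA from 53.6 ± 15.3 to 231 ± 40.9 (2.13 ± 0.29). The list passed camera (adjusted p = 2.12e-09, limma), not with an estimated correlation (adjusted p = 0.110). Of 31 squamous and hillock genes, which mark a squamous-like epithelial cell, 5 rose over all genes and 19 adjusted over the list alone (median log2 fold change 1.18; camera adjusted p = 3.23e-10, limma; adjusted p = 0.110 with an estimated correlation). KRT4 rose by 3.11 ± 0.48 on the log2 scale, SERPINB5 by 1.62 ± 0.25, and the calcium-binding protein S100A2 by 1.43 ± 0.19 to 2997 ± 169 FPKM. None of the squamous genes rose over all genes without BCH replicate 1 or without non-BCH replicate 1, 2 or 4, and over the 7 fits that left out 1 library 13 to 20 rose adjusted over the list alone, against 9 to 14 of the cornified envelope genes. In BCH replicate 1, 11 of the 20 cornified envelope and 16 of the 31 squamous genes were highest. The other BCH libraries also lay above every non-BCH library in the mean of both lists.

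Transcription factors of epidermal differentiation were higher too. Of 25 tested, 3 rose over all genes and 11 adjusted over the list alone, and none fell (median log2 fold change 0.80; camera adjusted p = 2.05e-06, limma; adjusted p = 0.262 with an estimated correlation). GRHL3, a factor of epidermal barrier formation, went from 32.0 ± 11.2 to 207 ± 85.0 FPKM, SOX15 from 12.3 ± 1.59 to 47.0 ± 16.1 and OVOL1 from 20.1 ± 4.77 to 72.5 ± 16.7. Of the 25, 13 were highest in BCH replicate 1. None rose over all genes without BCH replicate 1 or 2 or non-BCH replicate 1, 2 or 4, while 8 to 14 rose adjusted over the list alone with a library left out. Of 8 stress and hair follicle keratins, none passed over all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.00817, limma; adjusted p = 0.262 with an estimated correlation). These were the injury keratins KRT6A (156 ± 58.0 and 32.4 ± 13.0 FPKM in BCH and non-BCH), KRT6B (4.00 ± 1.71 and 0.463 ± 0.260) and KRT16 (179 ± 75.5 and 51.9 ± 15.4). KRT6A and KRT6B are near-identical, and how shared reads were split is not given in the sources used here.

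Of 23 genes of epidermal lipid and barrier synthesis, none passed over all genes and 10 rose adjusted over the list alone (median log2 fold change 0.83; camera adjusted p = 2.06e-05, limma; adjusted p = 0.262 with an estimated correlation). They included the lipid transporter ABCA12 (8.89 ± 3.29 and 1.70 ± 0.607 FPKM in BCH and non-BCH), the ceramide synthase CERS3 (16.8 ± 10.3 and 1.17 ± 0.672), SPTLC2 (36.7 ± 7.06 and 17.2 ± 2.62) and ABHD5 (59.6 ± 23.1 and 21.5 ± 3.52). In BCH replicate 1, 14 of the 23 were highest, and 4 rose adjusted over the list alone without that library, against 7 to 12 without another. Of 13 antimicrobial and alarmin genes, 1 rose over all genes and 7 adjusted over the list alone (median log2 fold change 1.32; camera adjusted p = 0.000266, limma; adjusted p = 0.262 with an estimated correlation). The gene that passed over all genes was PGLYRP3, a peptidoglycan recognition protein, at 6.46 ± 2.66 FPKM in BCH and 0.420 ± 0.279 in non-BCH. Of this list, 6 to 8 rose adjusted over the list alone with a library left out, and a gene passed over all genes only without BCH replicate 3. The keratinocyte lists were drawn up with the series title, which names a keratinocyte change in these samples, in view, so their direction is not independent evidence.

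**Figure D2:**
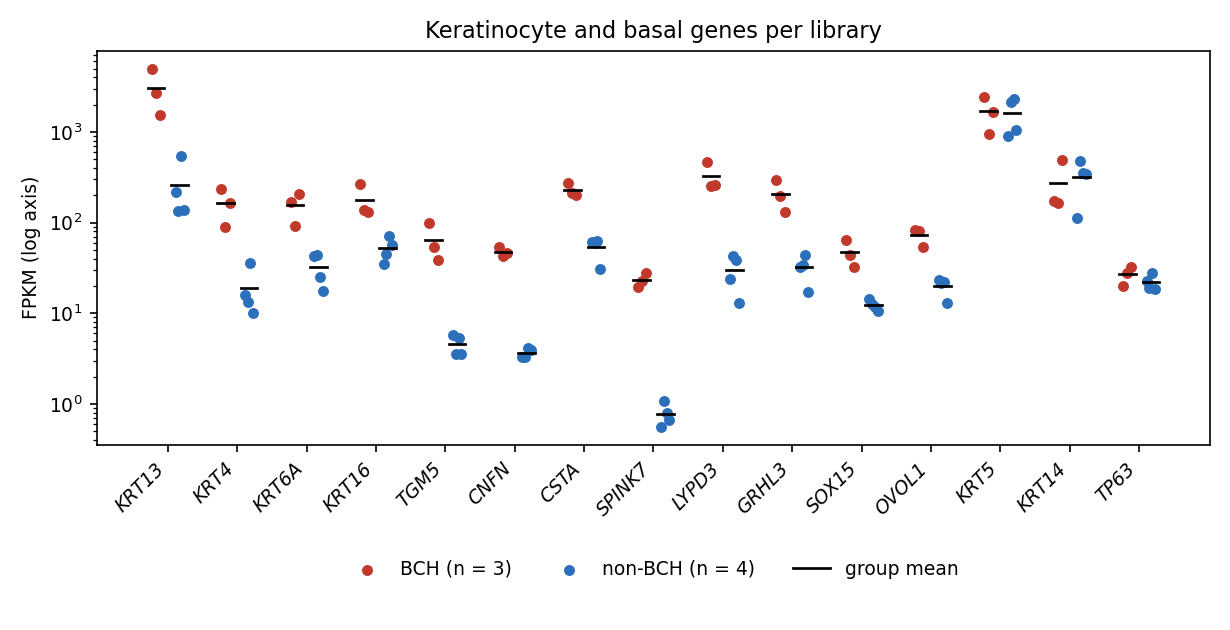
FPKM on a log axis of 15 keratinocyte and basal genes in the 3 BCH and 4 non-BCH libraries, each point being 1 library and each bar a group mean. The libraries of the groups did not overlap from KRT13 to OVOL1, whereas for KRT5, KRT14 and TP63 they did. KRT5, KRT14 and TP63 were named in advance, and the others for their change or low p, which favours genes without overlap.

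Stromal and matrix genes were lower in BCH. Of 21 fibroblast and smooth muscle genes, 5 fell over all genes and 14 adjusted over the list alone, none rose, and the median log2 fold change was -1.34 (camera adjusted p = 9.76e-10, limma; adjusted p = 0.110 with an estimated correlation). The collagen COL1A2 fell from 7.21 ± 1.71 to 1.504 ± 0.470 FPKM, the matrix proteoglycan LUM from 19.3 ± 4.06 to 5.96 ± 1.70, and the contractile genes CNN1 and MYLK from 11.1 ± 2.26 to 2.16 ± 1.13 and from 19.2 ± 5.39 to 3.77 ± 2.40. COL1A1, the partner chain of COL1A2, averaged 20.2 ± 4.46 FPKM in BCH and 16.04 ± 3.23 in non-BCH and did not pass (log2 fold change 0.32 ± 0.23; adjusted p = 0.447, limma). Of 34 genes of the extracellular matrix and basement membrane, 2 fell and 1 rose over all genes, and 15 fell and 1 rose adjusted over the list alone (median log2 fold change -1.14; camera adjusted p = 5.46e-07, limma; adjusted p = 0.110 with an estimated correlation). The basement membrane collagen COL4A2 fell from 24.5 ± 9.36 to 4.08 ± 0.914 FPKM and the protease inhibitor SERPINE2 from 43.4 ± 16.3 to 8.37 ± 3.40, and the gene that rose was ECM1. Of the 34 matrix genes, 14 were highest in non-BCH replicate 4, as were 7 of the 21 stromal genes, and COL4A2 stood at 36.1 FPKM there against 13.2 to 25.1 in the other non-BCH libraries. Without that library, as without non-BCH replicate 2, none of either list fell over all genes. Then 13 matrix genes and 9 of the 20 stromal genes tested without replicate 4 fell adjusted over the list alone, and the mean log2 fold changes were -0.71 and -1.16, against -0.79 and -1.21 with it. Over the 7 fits that left out 1 library, 9 to 15 matrix genes fell and 1 to 4 rose adjusted over the list alone, the fewest falls being without BCH replicate 1, and 9 to 15 stromal genes fell and 0 to 1 rose.

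**Figure D3:**
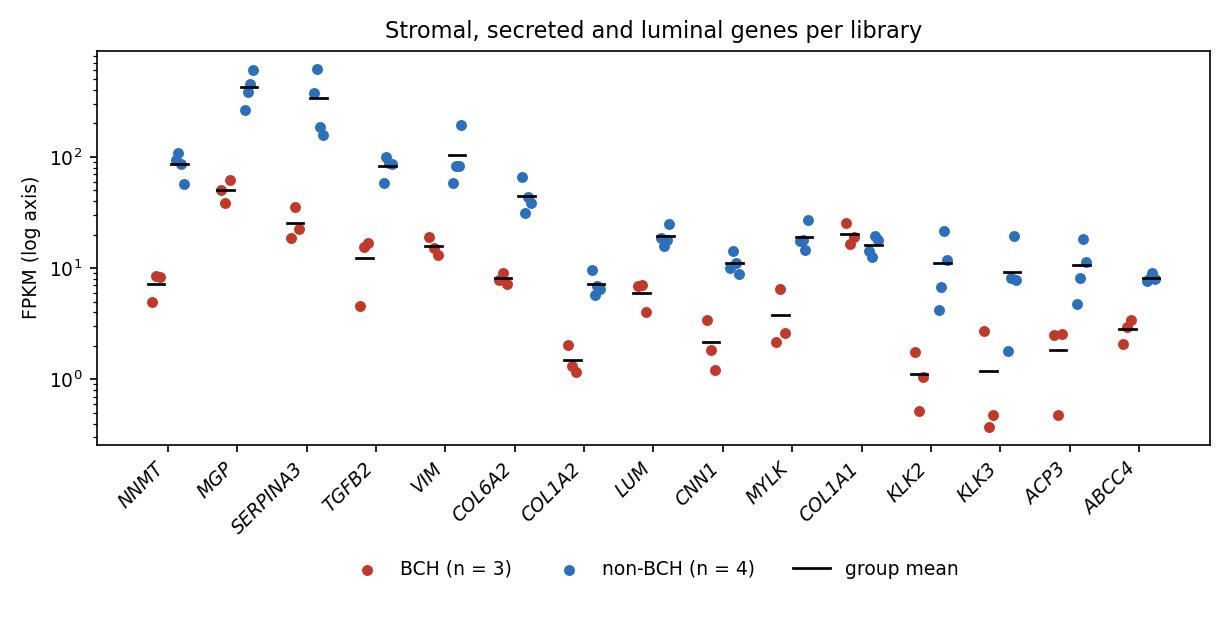
FPKM on a log axis of 15 stromal, secreted and luminal genes in the 3 BCH and 4 non-BCH libraries, each point being 1 library and each bar a group mean. The groups did not overlap for the genes drawn other than COL1A1 and KLK3. COL1A1 and KLK3 were named in advance, and the others for their change or low p, which favours genes without overlap.

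Other cell types of the gland were followed by the mean log2(FPKM + 1) of their marker lists. The list means of basal, luminal, fibroblast and smooth muscle and neuroendocrine genes were lower in every BCH library than in any non-BCH library, and that of urothelial genes was higher. An exact two-sided permutation test of 3 against 4 libraries cannot go below p = 0.0571, the value these 5 of the 9 lists reached (adjusted p = 0.103, exact permutation test). The neuroendocrine list held 2 tested genes, each of which overlapped between the groups. Its means were apart narrowly, at 1.025 in BCH replicate 1 and 1.038 in non-BCH replicate 2. The endothelial list averaged 1.55 ± 0.302 in BCH and 2.66 ± 1.18 in non-BCH, where replicate 4 stood at 4.33 and the other 3 libraries between 1.54 and 2.45 (exact permutation p = 0.114). Each of the 13 tested endothelial genes was highest in non-BCH replicate 4, and none passed (median log2 fold change -1.08). Without that library the median was -0.65, and without non-BCH replicate 3 it was -1.42 and 2 genes fell adjusted over the list alone. The lowest p belonged to CLDN5, at 0.665 ± 0.427 FPKM in BCH and 4.58 ± 2.51 in non-BCH, and ENG, at 3.72 ± 0.979 and 7.89 ± 3.03. The endothelial list passed camera (adjusted p = 0.000304, limma), not with an estimated correlation (adjusted p = 0.495).

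**Figure D4:**
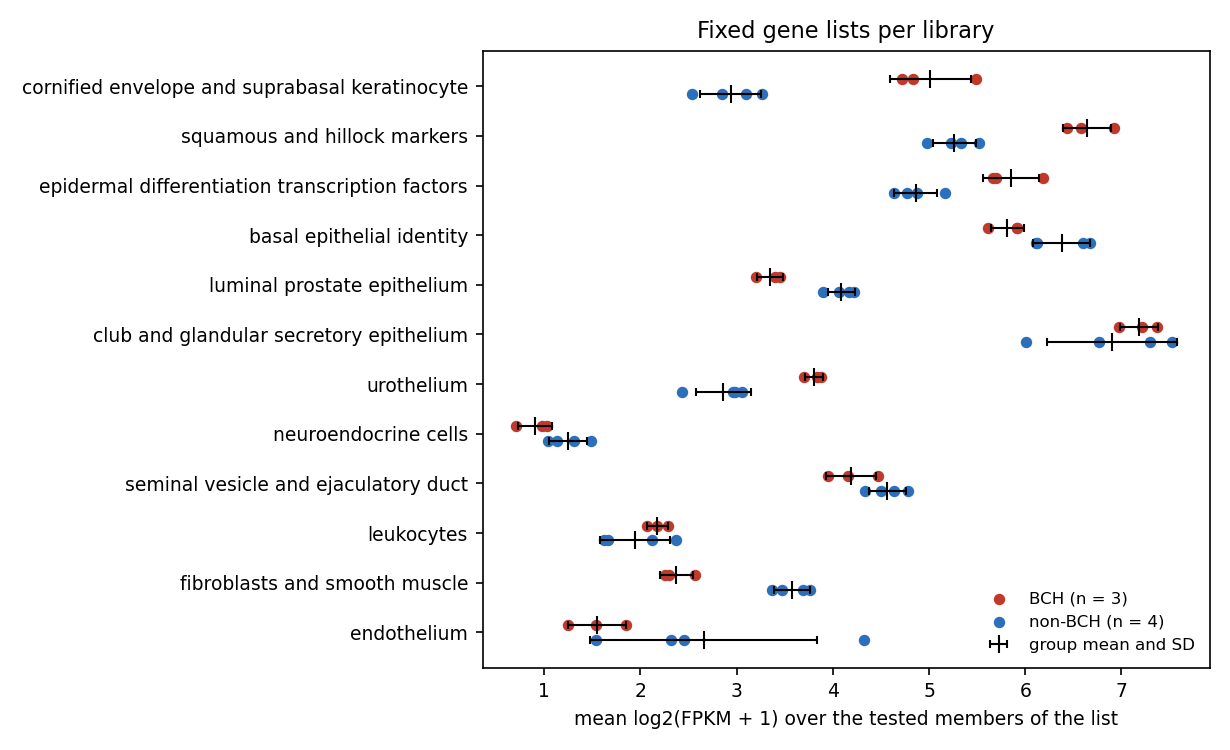
Mean log2(FPKM + 1) over the tested members of 12 fixed gene lists in each library, with points for libraries, ticks for group means and bars for SD (n = 3 BCH, n = 4 non-BCH). The groups were apart for the 3 keratinocyte lists and for the basal, luminal, urothelial, neuroendocrine and stromal lists, and non-BCH replicate 4 stood at 4.33 on the endothelial list. The neuroendocrine list, of 2 genes, was apart narrowly, at 1.025 in BCH replicate 1 and 1.038 in non-BCH replicate 2.

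Of 28 genes of basal identity, none passed over all genes and 2 fell adjusted over the list alone (median log2 fold change -0.57; camera adjusted p = 0.000410, limma; adjusted p = 0.262 with an estimated correlation). These were the receptor NOTCH4, at 10.4 ± 4.05 FPKM in BCH and 34.97 ± 6.36 in non-BCH, and the mucin-type glycoprotein PDPN, at 5.25 ± 4.02 and 21.9 ± 6.11. With a library left out, 0 to 7 basal genes fell in this way, none without non-BCH replicate 2 or 4. Of 16 luminal genes, none passed over all genes, and 7 fell and 1 rose adjusted over the list alone (median log2 fold change -0.40; camera adjusted p = 0.0167, limma; adjusted p = 0.185 with an estimated correlation). The kallikrein KLK2 averaged 1.11 ± 0.622 FPKM in BCH and 11.1 ± 7.60 in non-BCH, and the acid phosphatase ACP3 1.85 ± 1.19 and 10.6 ± 5.78, while RDH11, a retinol dehydrogenase, rose, at 79.2 ± 14.5 and 42.9 ± 0.986. KLK3, which encodes prostate-specific antigen, averaged 1.19 ± 1.33 and 9.26 ± 7.36 FPKM and did not pass (adjusted p = 0.147, limma). The 7 luminal genes that fell became none without BCH replicate 2 and 2 to 5 without another library, and the median ran from -0.13 without non-BCH replicate 1 to -0.69 without BCH replicate 3. Of 19 androgen response genes, 1 fell over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0254, limma; adjusted p = 0.194 with an estimated correlation). The one was the transporter ABCC4, at 2.81 ± 0.687 and 8.14 ± 0.571 FPKM, and the other was KLK2. With a library left out, 1 to 3 of these genes fell adjusted over the list alone, and over all genes 1 did without BCH replicate 3 and none without another.

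Of 11 urothelial genes, none passed over all genes and 6 rose adjusted over the list alone (median log2 fold change 1.01; camera adjusted p = 0.00224, limma; adjusted p = 0.110 with an estimated correlation). They included the uroplakins UPK2 (3.60 ± 1.66 and 0.560 ± 0.185 FPKM in BCH and non-BCH) and UPK1A (5.88 ± 3.36 and 1.29 ± 0.461), FOXQ1 (39.0 ± 4.50 and 19.6 ± 6.88) and PPARG (97.0 ± 41.6 and 32.6 ± 16.9). The 6 became none without BCH replicate 1 and 1 to 5 without another library. The 26 club and glandular secretory genes did not pass as a list (camera adjusted p = 0.797, limma), with 3 higher and 1 lower adjusted over the list alone. MUC4, a membrane mucin, was at 459 ± 162 and 79.3 ± 44.9 FPKM, CLDN4 at 2292 ± 831 and 739 ± 211, SLPI at 1064 ± 391 and 369 ± 137, and the protease MMP7 lower, at 302 ± 93.5 and 1159 ± 431. No club gene passed without BCH replicate 1 or 2. The neuroendocrine list had 2 tested genes, too few for camera, SCG2 at 1.004 ± 0.474 and 1.53 ± 0.193 FPKM and CHGB at 0.794 ± 0.338 and 1.28 ± 0.650. The seminal vesicle list had 4, of which PAX8 fell adjusted over the list alone (4.38 ± 2.38 and 9.57 ± 0.290 FPKM). None of 10 leukocyte genes passed (camera adjusted p = 0.984, limma), CD68 standing at 107 ± 43.8 and 31.7 ± 19.8 FPKM and IL7R at 0.960 ± 0.515 and 2.46 ± 0.744. Adjusted over the list alone, 3 leukocyte genes rose without BCH replicate 3 and 1 without non-BCH replicate 1.

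Cytokine and signalling lists held members in both directions. Of 33 cytokine and chemokine genes, TGFB2 fell over all genes, and 7 fell and 2 rose adjusted over the list alone (median log2 fold change -0.44; camera adjusted p = 0.00266, limma; adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, 1 cytokine gene fell and none rose without BCH replicate 1 or 3 or non-BCH replicate 1 or 4, and up to 10 fell and 3 rose without another library, with medians from -0.31 to -0.85. Over all genes, 1 fell only without BCH replicate 1 or 3, and 1 rose without non-BCH replicate 2. In non-BCH replicate 2, 15 of the 33 were highest, and the list means of the groups overlapped (exact permutation p = 0.229). Of 29 interferon response genes, none passed over all genes, and OASL (45.6 ± 17.5 and 6.83 ± 5.02 FPKM in BCH and non-BCH) and MX1 (41.8 ± 8.34 and 16.1 ± 5.14) rose and IFITM1 (56.2 ± 27.3 and 215 ± 30.4) fell adjusted over the list alone (camera adjusted p = 0.424, limma). Of 18 Notch genes, none passed over all genes and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.510, limma). The receptor NOTCH3 averaged 69.2 ± 12.2 and 22.3 ± 11.8 FPKM and the target HES1 469 ± 107 and 190 ± 75.1, against NOTCH4 and the ligand DLL1, the latter at 3.35 ± 1.83 and 11.1 ± 4.74. Of 23 Wnt and Hedgehog genes, none passed over all genes, and the ligand WNT5A rose (10.5 ± 2.59 and 2.50 ± 1.51 FPKM) and the Wnt inhibitor WIF1 fell (4.48 ± 4.06 and 36.4 ± 24.4) adjusted over the list alone. That list had a camera adjusted p of 0.0196 (limma; adjusted p = 0.262 with an estimated correlation) and a median log2 fold change of -0.45. Of 20 ErbB genes, the receptor ERBB3 alone rose adjusted over the list alone (281 ± 84.6 and 82.8 ± 28.8 FPKM), and camera, with a negative direction against a positive median of 0.23, gave adjusted p = 0.797 (limma). These counts also moved when 1 library was left out. Over each list alone, 0 to 5 interferon genes rose, 0 to 6 Notch genes rose and 1 to 3 fell, 0 to 2 Wnt and Hedgehog genes rose and 0 to 4 fell, and 0 to 1 ErbB genes rose and 0 to 2 fell, with an ErbB median from 0.08 to 0.30.

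Of 21 retinoid genes, none passed over all genes, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.359, limma). The receptor RARG averaged 78.0 ± 9.61 and 34.96 ± 7.37 FPKM in BCH and non-BCH, the binding protein CRABP2 358 ± 158 and 108 ± 37.5, RDH10 25.7 ± 3.42 and 13.5 ± 2.98, and RARRES2, which fell, 4.59 ± 0.967 and 10.2 ± 1.44. With a library left out, 0 to 6 retinoid genes rose, none without BCH replicate 1, and 0 to 2 fell. None of 18 steroid hormone genes passed (camera adjusted p = 0.0577, limma), with SULT2B1 at 108 ± 35.1 and 25.8 ± 17.2 FPKM and AKR1C3 at 59.7 ± 37.9 and 19.2 ± 11.1. Without non-BCH replicate 1, 5 of them rose and 1 fell adjusted over the list alone, and without non-BCH replicate 2, 1 rose. Of 33 genes of oxidative stress and xenobiotic metabolism, GPX3 fell over all genes, and 5 rose and 2 fell adjusted over the list alone (median log2 fold change 0.78; camera adjusted p = 0.000410, limma; adjusted p = 0.495 with an estimated correlation). In BCH replicate 2, 20 of the 33 were highest, and its list mean was 7.21 against 6.35 and 6.52 in the other BCH libraries. The groups overlapped, non-BCH replicate 1 standing at 6.39 (exact permutation p = 0.114), and without BCH replicate 2 the mean log2 fold change was 0.62 against 0.88 with it. Over the 7 fits, 1 to 7 of these genes rose and 1 to 2 fell adjusted over the list alone, and over all genes 1 fell only without non-BCH replicate 3 or 4 and 1 rose without BCH replicate 3.

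None of 25 glycolysis and hypoxia genes passed singly, with VEGFA at 343 ± 128 and 146 ± 15.3 FPKM in BCH and non-BCH and the glucose transporter SLC2A1 at 489 ± 400 and 100.3 ± 32.7. That list passed camera (adjusted p = 0.000892, limma; adjusted p = 0.495 with an estimated correlation), as did 75 genes of nuclear oxidative phosphorylation (adjusted p = 0.00159, limma; adjusted p = 0.779 with an estimated correlation) and 77 ribosomal protein genes (adjusted p = 0.0488, limma; adjusted p = 0.865 with an estimated correlation). In BCH replicate 1, 16 of the 25 glycolysis and hypoxia genes were highest, SLC2A1 standing at 948 FPKM there against 307 and 213 in the other BCH libraries. The glycolysis list means of the groups overlapped (exact permutation p = 0.114), and without BCH replicate 1 their mean log2 fold change was 0.33 against 0.64 with it. Without BCH replicate 3, 4 of them rose adjusted over the list alone, as did 4 oxidative phosphorylation genes without non-BCH replicate 2. The list means of the groups overlapped for oxidative phosphorylation (exact permutation p = 0.286) and for ribosomal proteins (exact permutation p = 0.457), and 34 of the 75 and 39 of the 77 genes were highest in non-BCH replicate 2. The mean log2 fold change of oxidative phosphorylation ran from 0.17 without non-BCH replicate 4 to 0.45 without non-BCH replicate 2, and that of the ribosomal list from 0.06 without BCH replicate 1 to 0.31 without non-BCH replicate 2. In the oxidative phosphorylation list COX7B stood at 321 ± 37.8 and 168 ± 35.4 FPKM and NDUFA1 at 85.0 ± 13.4 and 48.6 ± 14.03. In the ribosomal list RPS29 stood at 1553 ± 406 and 936 ± 157 and RPS27L at 52.0 ± 17.02 and 113 ± 23.0. No gene of the cell cycle list (26 tested), of the immediate early and dissociation list (29) or of the mitochondrial genome (13) passed, and camera gave adjusted p of 0.984, 0.188 and 0.984 (limma). Their lowest p belonged to PLK1 (8.12 ± 3.11 and 2.88 ± 0.899 FPKM) and TYMS (4.43 ± 1.60 and 9.60 ± 1.85), to NR4A3 (4.59 ± 2.60 and 12.9 ± 3.16) and HSPB1 (2998 ± 1502 and 1003 ± 338), and to MT-ND6 (4482 ± 1856 and 1791 ± 167) and MT-ND5 (6391 ± 1527 and 4374 ± 1140). Adjusted over the list alone, 1 cell cycle gene rose without BCH replicate 3 and 1 mitochondrial gene without BCH replicate 2. In the immediate early list 1 gene fell without BCH replicate 1 and 1 rose without BCH replicate 3. The medians of the immediate early, mitochondrial, interferon, ErbB and ribosomal lists turned from positive to negative under quantile normalization, the ribosomal one from 0.21 to -0.19. Leaving out 1 library also turned medians negative, the mitochondrial one to -0.23 without non-BCH replicate 1, the interferon one to -0.14 without non-BCH replicate 3 and the club one to -0.08 without non-BCH replicate 4. Camera's direction for the cell cycle list was negative against a positive median of 0.20. In BCH replicate 2, 17 of the 26 genes were highest. Without that library 20 genes of the list were tested, with a median of -0.33, so some of the 26 entered only through it.

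In all, camera passed 19 of 29 lists, 11 higher and 8 lower in BCH, and fry passed 11. With an estimated correlation camera passed none, and 7 lists had an unadjusted p under 0.05. Lists with no gene past the threshold over all genes gained 1 in some fits that left out a library, namely the lipid, luminal, interferon, Notch and Wnt and Hedgehog lists. The count of called genes was 930 among protein-coding genes alone (587 higher, 343 lower), a choice made after seeing the data, 39 with no filter, 288 at a mean of at least 5 FPKM and 350 with a robust variance, and it was 39, 72 and 267 without BCH replicates 1, 2 and 3 and 50, 45 and 60 without non-BCH replicates 1, 2 and 4. The share of calls higher in BCH was 64.3%, against 53.4% under quantile normalization and 32.2% after rescaling to TPM. At a mean of at least 1 TPM 14870 genes were tested, with a median log2 fold change of -0.27, against 0.05 over the 17527.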

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

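The tests of a stromal share on a second set of marker genes and of the endothelial genes on a second list were set before their results were seen. The tests of endothelial cells as the origin of the stromal difference, of scaling, of a single library, of another epithelial cell type, of leukocytes or stromal cells beside the endothelial cells and of other splits of the libraries were chosen after.

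In the 4 non-BCH libraries, 9 of 127 tested values had 1 library far from the other 3, by the gap to its nearest neighbour over the group's range, where chance gives about 1 in 20. The urothelial list mean of non-BCH replicate 4 was the lowest, 2.43 against 2.96 for the next (0.847 of the range). The Wnt and Hedgehog list mean of non-BCH replicate 1 was the lowest, 2.85 against 3.09 (0.884). On the log2(FPKM + 1) scale, CSTA was lowest in non-BCH replicate 4, at 4.98 against 5.94 (0.952), and so was OVOL1, at 3.81 against 4.51 (0.870). IL7R was lowest in non-BCH replicate 3, at 1.23 against 1.91 (0.946), as was RARRES2, at 3.17 against 3.55 (0.917). SERPINE2 was highest in non-BCH replicate 1, at 6.11 against 5.26 (0.859), and so was VEGFA, at 7.41 against 7.15 (0.837). COX7B was highest in non-BCH replicate 2, at 7.79 against 7.26 (0.881).

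Stromal genes were lower in BCH although the gate on CD326 should remove stroma from both groups. Endothelial cells in non-BCH replicate 4 were not the origin, since without that library the fibroblast and smooth muscle list mean still differed by -1.16 on the log2 scale. Of 19 tested genes on second fibroblast and smooth muscle lists, 89.5% had a negative log2 fold change, against 46.4% of all tested genes. The filter took the mean over all 7 libraries, so genes averaging under 1 FPKM in BCH were tested only through non-BCH. Such genes had to fall, as CXCL12 did, at 0.65 FPKM or less in BCH and 0.79 to 2.91 in non-BCH. The 89.5% is thus raised by the filter and is not independent support. A larger share of fibroblasts and smooth muscle cells in the non-BCH sorts is a candidate explanation. In the BCH libraries 14 of the 19 averaged at least 1 FPKM, and of the abundant stromal genes TAGLN averaged 85.3 and 367 FPKM in BCH and non-BCH and SPARC 16.8 and 105, while COL1A1 averaged 20.2 and 16.04 and FBLN1 50.6 and 31.8. Lower expression within the basal cells of BCH would lower such genes too and stays open, as untested.

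Keratinocyte genes were higher in BCH. For the cornified envelope list scaling between libraries was not the origin, since its median log2 fold change was 1.77 under quantile normalization. The medians of the other keratinocyte lists stayed positive but shrank there. They were 1.16 for antimicrobial, 0.81 for squamous, 0.69 for transcription factor, 0.63 for lipid and 0.55 for stress keratin genes. After rescaling to TPM the transcription factor and stress keratin medians were 0.385 and 0.363. A part of scaling in these other lists is not excluded. A single library was not the whole origin of the cornified envelope rise, although 11 of its 20 genes were highest in BCH replicate 1. The lowest median of that list over the 7 fits with 1 library left out was 1.73. The urothelial list rose with the keratinocyte lists, by 0.947 on the log2 scale and without overlap between the groups, and in bulk libraries a larger share of another epithelial cell type in the BCH sorts cannot be told apart from a change within basal cells. The difference between the diagnoses stays open as a biological hypothesis, untested by any other sample.

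Endothelial genes stood high in non-BCH replicate 4, with SELE at 192 FPKM and PLVAP at 86.2 against at most 22.3 and 22.5 in any other library. On a second endothelial list, 15 of the 18 tested genes (83.3%) were highest in this library, and 11 of the 18 averaged at least 1 FPKM in BCH. The filter took the mean over all 7 libraries, so some genes low elsewhere were tested only through this library. Such genes had to be highest there, as SOX18 was, at 8.22 FPKM against 2.2 or less elsewhere. The 83.3% is thus raised by the filter and is not independent support. Endothelial cells in the sorted fraction are a candidate explanation, although the gate on CD326 should remove them. The tested leukocyte genes did not rise with the endothelial genes. Of these 10 genes 1 (10%) was highest in this library, and its leukocyte list mean of 1.62 was the lowest of the 7. Only 10 of the 34 leukocyte genes were tested, and PTPRC was under the filter, at 0.518 FPKM in this library. A small share of leukocytes is therefore not excluded. Stromal cells beside the endothelial cells stay open. Of the fibroblast and smooth muscle genes 33.3% were highest in this library, as many as in non-BCH replicate 1, whose endothelial list mean was 2.31. The stromal list means of non-BCH replicates 4 and 1 were 3.77 and 3.69, and no biological explanation was tested.

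The 35 splits of the 7 libraries into 3 and 4 gave the 143 called genes in 1 split, the real one, and at most 17 genes in another. Chance is thus an unlikely origin of the count but is not excluded, since 1 of 35 is the smallest share these splits can give. For gene lists the real split was also the 1 with as many calls, at 19, but another split reached 18 and the median of the others was 10. Camera with its preset correlation thus called many lists in libraries grouped without regard to diagnosis, and a called list there carries little weight of its own. Among protein-coding genes alone the real split called 930 genes and no other split more than 1.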

How the results depend on the processing

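No paired analysis was possible because each library came from another patient and the labels give no number that links patients of different groups. The absolute depth was unknown, which limits the reading of low values most. The 143 called genes (92 higher, 51 lower in BCH) became 39 (30 and 9) with no filter, 288 (203 and 85) at a mean of at least 5 FPKM, 350 (230 and 120) with a robust variance, 942 (637 and 305) at an adjusted p under 0.1, and 930 (587 and 343) among protein-coding genes alone, which was chosen after seeing the data. Rescaling to TPM tested 14870 genes at a mean of at least 1 TPM in place of 17527. It kept the total at 143, with 46 higher and 97 lower, and 91 of these were among the main calls. This rescaling divides each library by its FPKM sum, which was 2141737 to 2961901 in BCH and 1542295 to 2057080 in non-BCH. It therefore lowered the BCH values against the non-BCH values by construction. Quantile normalization gave 163 genes (87 and 76), 136 of them main calls. With protein-coding genes alone the prior degrees of freedom of limma rose from 2.55 to 5.32, and the median residual SD of the genes left out was 0.557 against 0.350 for those kept. Leaving out each library in turn gave 39 to 267 genes (26 to 195 higher, 13 to 72 lower): 39, 72 and 267 without BCH replicates 1, 2 and 3, and 50, 45, 99 and 60 without non-BCH replicates 1, 2, 3 and 4. The cause of these differences between settings was not tested. The 34 named genes called over all genes had the same direction under each of the 10 settings run for them, and between 7 (without BCH replicate 1) and 27 (without BCH replicate 3) of them stayed past the threshold with a library left out, 33 with a pseudocount of 0.1 and 34 under quantile normalization and under median-ratio rescaling. Of the 19 called lists, 0 passed with an estimated correlation and 11 with fry, and the other settings gave 14 to 20 lists. The cornified envelope list had an adjusted p of 0.110 with an estimated correlation (camera), and between 6.16e-12 and 0.00331 under the other settings. The ribosomal protein list reversed under quantile normalization (camera adjusted p = 0.00193, lower in BCH), and the cause was not tested. Cell type lists without overlap between the groups numbered 5 of 9, and 4 to 7 under the alternatives.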

Other observations

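Some genes of the fixed lists, chosen after their values were seen, set single libraries apart within a group. Several heat shock chaperones of the immediate early and dissociation list stood high in BCH replicate 1, with DNAJB1 at 1404 FPKM against 140 to 262 in the other 6 libraries, HSPH1 at 956 against 133 to 220 and HSP90AA1 at 2419 against 345 to 579. The near-identical pair HSPA1A and HSPA1B stood at 748 and 479 FPKM there. Of the 29 immediate early and dissociation genes, 19 were highest in that library. In BCH replicate 2, 17 of the 26 tested cell cycle genes were highest, with MKI67 at 4.56 FPKM against 0.930 or less elsewhere and TOP2A at 5.51 against 2.17 or less. Without that library 20 cell cycle genes were tested, so some of the 26 passed the filter only through it. The uroplakin UPK1B stood at 97.7 FPKM in BCH replicate 2 and at 10.95 or less in the other libraries. The cornified envelope gene SPRR3 stood at 1756, 124 and 197 FPKM in the BCH libraries and at 1.16 to 14.4 in non-BCH. Of the 29 interferon genes 15 were highest in non-BCH replicate 1, where CXCL10 stood at 191 FPKM.

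Among protein-coding genes tested alone, several genes outside the fixed lists, chosen after their values were seen, also passed. SCEL, a cornified envelope precursor, rose by 2.87 ± 0.32 on the log2 scale (adjusted p = 0.00442, limma), the serine protease TMPRSS11D by 3.62 ± 0.60 (adjusted p = 0.0122, limma) and the oxidase DUOX2 by 2.87 ± 0.49 (adjusted p = 0.0126, limma). The actin-binding gene CALD1 fell by 1.93 ± 0.23 (adjusted p = 0.00496, limma), the complement protease C1R by 2.22 ± 0.26 (adjusted p = 0.00448, limma) and the secreted protein IGFBP7 by 2.50 ± 0.39 (adjusted p = 0.0106, limma). Members of the fixed lists that passed over the list alone and were left out above were again chosen after their values were seen. They included the alarmins S100A8 (203 and 16.4 FPKM in BCH and non-BCH) and S100A9 (1132 and 164), the peroxidase GPX2 (897 and 156) and the matrix protein TNC (25 and 133). From the cytokine list they included the chemokine CCL2 (283 and 1632), the cytokine IL33 (3.65 and 19.8) and the inhibitor IL1RN (421 and 77.5). No gene of that list, IL1RN included, rose over the list alone without BCH replicate 1, 2 or 3 or non-BCH replicate 1 or 4. Without BCH replicate 1 or 3 or non-BCH replicate 1 or 4 only 1 fell, so CCL2 and IL33 did not both pass there.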
